A study of Mus musculus with 12 samples.

How the data were processed

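Bulk RNA-seq of total RNA covered 12 mouse libraries: cortex of floxed Srsf10 mice without Nestin-Cre (control) and with it (labelled cKO), and NPC labelled control and knockdown, 3 libraries each. Per the labels, the authors aligned the reads with HISAT2 (version not stated) to mm10, and the deposited table holds raw counts per gene, one column per library. The program that counted the reads and its annotation are not given in the sources used here. The values were checked to be whole numbers with a different total in each library. Gene positions came from GENCODE release 21 for mouse, on the same build, which held 34065 of the 34102 identifiers. The table holds 1 count per gene and library, so splicing, exon use and deletion of a floxed exon were not analysed here.

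Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3), and genes were kept by filterByExpr in each comparison. Each comparison was tested with the quasi-likelihood test of edgeR on its own 6 libraries, and the difference between the 2 systems by the interaction contrast in 1 fit of all 12. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Group levels are counts-per-million (CPM) with TMM factors as mean ± SD over 3 libraries, except library values and the marker levels of control libraries, which use total counts. Log2 fold changes are treated minus control with their standard error, and intervals are 95%. Shared replicate numbers were checked as pairs: residuals of same-numbered libraries correlated in NPC and not in cortex (0.02, -0.17 and -0.02), so NPC results are given without and with the replicate block. Replicates of the same group differed by more than counting noise, so none is a copy of another.

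Before the data were examined, 31 gene lists for cell types, pathways and RNA composition were fixed. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated one. The directional test of fry was also used. Lists needed at least 5 tested members, which left 29 in cortex and 26 in NPC. The mitochondrial genome list has 0 genes in the table, and 0 of 9 replication-dependent histone genes passed the filter. None of the lists called with the preset correlation passed with an estimated one. Named genes followed a rule fixed at the same time: Srsf10 and Nasp; the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, without unnamed gene models; the 4 members with the smallest adjusted p of each called list and the first 3 of every list; up to 5 genes called in both systems; and the 5 largest interaction terms in each direction. Cnr2, Pnrc2, Ensa, Gm10052, Xist, Ddx3y and genes given only as library or system levels were named after their values were seen.

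Overlap between systems was tested with Fisher's exact test (two-sided) without Srsf10. Other settings fixed before the data were examined were RLE size factors, no count filter, DESeq2 1.42.0, 1 fit of all libraries, the replicate block, a 1.5-fold minimum and leaving out each library. Chosen after seeing the data were sex as a covariate (male above 10 CPM of Ddx3y), leaving out the libraries above 1000 CPM of Ttr, the alternatives of the blocked NPC result, the overlap with the block in NPC alone, and leaving out genes with the hexamers described next. A setting meant for normalised units did not apply to counts and was not run.

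Annotated 3′ UTRs of at least 50 bases were searched for 7-mers in NPC genes with a mean log2 CPM of at least 2, also after seeing the data. The 7-mer whose carriers lay lowest was picked among 16066 on 5706 genes of odd-numbered autosomes. It was tested on the other 4887 genes with 100000 permutations of genes (Python 3.11.15, numpy 2.4.6, scipy 1.17.1).

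The procedure was tested on simulated data with planted changes. With 3 libraries against 3 it recovered 56.7%, 97.0% and 98.5% of genes changed 1.5-fold, 2-fold and 3-fold in cortex, with 6.67% false calls. In NPC it recovered 38.8%, 85.1% and 97.0% (5.77% false), with the replicate block 49.3%, 95.5% and 100% (10.9% false), and for the interaction 13.4%, 50.7% and 89.4% (3.77% false). Changes were planted in genes with a mean of at least 5 CPM, in 1 simulated set per comparison. Dispersions were estimated without a treatment term, and only the simulation with the replicate block held pair effects. These rates thus describe the simulated data and need not hold for the real fits. The 7-mer search recovered the planted sequence in 20 of 20 runs. Libraries held 26074094 to 36713205 counts, and replicates differed by more than counting noise, so the spread between libraries limits the precision as well as depth; the smallest share of other groupings that 3 against 3 libraries allow is 1 in 10. Figures were drawn with matplotlib 3.10.9.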

Results

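RNA was sequenced from the cortex of mice labelled as Srsf10 conditional knockouts (cKO) and from cultured mouse neural progenitor cells (NPC) labelled as Srsf10 knockdowns, each beside its controls. Srsf10 encodes a splicing factor of the SR protein family, proteins that bind RNA and steer which exons are joined. The 12 libraries form 4 groups of 3. Both cortex groups carry floxed Srsf10, and only the cKO group carries the Nestin-Cre transgene, which makes Cre recombinase in neural progenitors and their descendants. No group carries Nestin-Cre without floxed Srsf10, so the cortex comparison cannot tell loss of Srsf10 from an effect of the transgene. By the labels, the NPC of both groups were harvested 72 h after viral infection at a multiplicity of 30. Which virus the control cells received is not said in the labels. The libraries held 26074094 to 36713205 counts over 34102 genes, from 32560159 in cortex and up to 30608918 in NPC. The age of the mice is not given in the sources used here, nor is it stated that each library came from a separate animal or culture.

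Within each system, the control libraries carried markers of neurons in cortex and of progenitors in culture, though some listed markers were present in both. In control cortex, the neuronal genes Tubb3 and Dcx stood at 2278 ± 314 and 2639 ± 390 CPM (counts-per-million of the library total; mean ± SD, n = 3), and the deep-layer marker Tbr1 at 221 ± 6.24 CPM. The progenitor gene Nes stood at 133 ± 4.82 CPM in control cortex (n = 3). In control NPC, Nes reached 1930 ± 46.3 CPM, while Tubb3 stood at 12.5 ± 1.30 CPM (n = 3). Olig2, a transcription factor of glial and ventral progenitors, reached 1059 ± 21 CPM there. The neuronal gene Map2 was high in both systems, at 1565 ± 180 CPM in control cortex and 1046 ± 64.8 CPM in control NPC. The radial glia gene Pax6 stood at 21.1 ± 3.27 and 25.9 ± 1.43 CPM (n = 3 each). How reads were counted is not given in the sources used here, and whether both systems were counted alike was not tested. Gapdh, for example, stood at 20.5 ± 2.30 CPM in control cortex and 70.1 ± 6.19 CPM in control NPC (n = 3 each), so a level that differs between the systems is not read as a difference in expression. The Y-linked gene Ddx3y and the X-inactivation transcript Xist marked 1 female and 2 males among the control cortex libraries, and 2 females and 1 male among the cKO libraries. In both NPC groups replicates 1 and 2 were female and replicate 3 was male. Transcripts of the choroid plexus gene Ttr were abundant in control cortex replicate 2 (1194 CPM) and cKO replicate 3 (1082 CPM), and stood between 2.35 and 100 CPM in the other 4 cortex libraries.

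The Srsf10 count itself was tested first, because both comparisons rest on its loss. Srsf10 (ENSMUSG00000028676, chromosome 4, 135855747 to 135869908, plus strand, mm10) stood at 207 ± 11.5 CPM in control cortex and 211 ± 20.8 CPM in the libraries labelled cKO (n = 3 each). The log2 fold change was 0.03 (SE 0.08, 95% interval -0.15 to 0.21, adjusted p = 0.917). In NPC it stood at 233 ± 13.7 CPM in controls and 226 ± 11.9 CPM in the libraries labelled knockdown (log2 fold change -0.05, SE 0.07, 95% interval -0.21 to 0.12, adjusted p = 0.774). With the replicate numbers as pairs, the value was -0.05 (95% interval -0.15 to 0.06, adjusted p = 0.530). The lower bound of the unpaired NPC interval corresponds to 0.865 of the control level, so a larger loss of Srsf10 transcript is outside the interval. A count over the whole gene does not test whether a floxed part was deleted, nor whether less protein was made. The groups are therefore named by their labels, "labelled cKO" and "labelled knockdown", and directions rest on those labels.

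**Figure D1:**
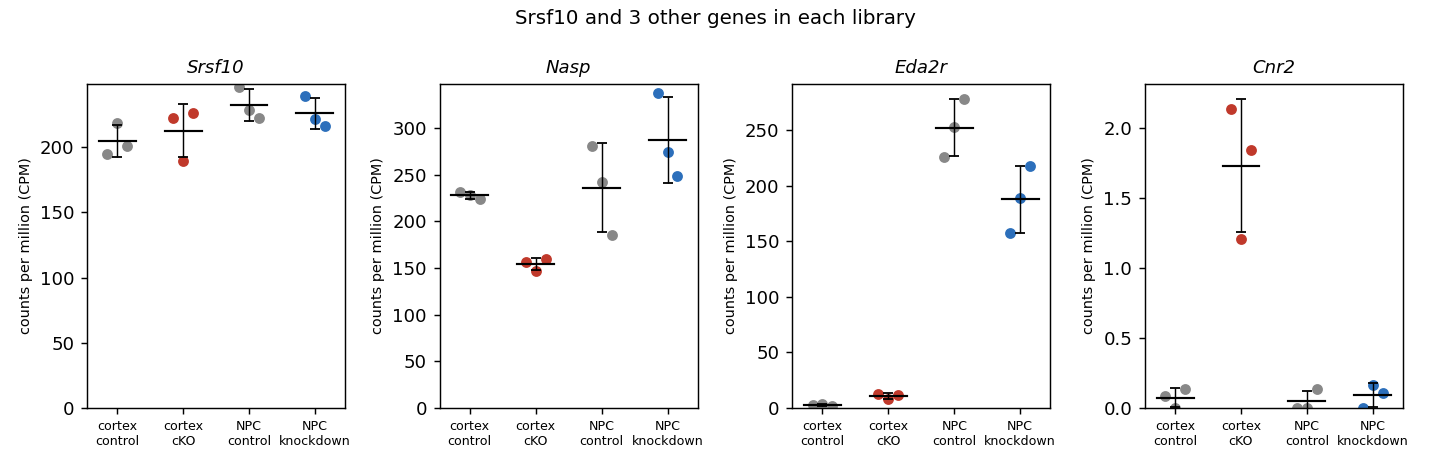
CPM of Srsf10, Nasp, Eda2r and Cnr2 in each of the 12 libraries, by group, with the mean (bar) and SD (whiskers) of 3 libraries. Srsf10 differs little between groups, from 190 to 226 CPM in the cKO libraries against 195 to 219 CPM in their controls, while Nasp is lower and Eda2r and Cnr2 are higher in all 3 cKO libraries.

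Cortex of mice labelled cKO showed few gene changes, most of them falls of less than 2-fold. Nasp (ENSMUSG00000028693), which encodes a chaperone of histones, stood at 230 ± 6.05 CPM in controls and 153 ± 7.07 CPM in cKO cortex (n = 3 each; log2 fold change -0.58, SE 0.06, adjusted p = 0.00692). The falls of Gramd1a, a carrier of cholesterol between membranes, and of Ensa, a regulator of a mitotic phosphatase, had the smallest adjusted p in this comparison. Gramd1a fell by 0.98 (log2, SE 0.08, adjusted p = 0.00341) and Ensa by 0.65 (SE 0.06, adjusted p = 0.00401); Ensa was named after its values were seen. Eda2r, a receptor of ectodysplasin A2 whose gene p53 activates, rose from 2.60 ± 0.837 to 10.6 ± 2.69 CPM (log2 fold change 2.04, SE 0.27, adjusted p = 0.0213). The other falls chosen by the fixed rule were Slc26a7 (log2 fold change -0.81), Gpr17 (-0.79), Atp6v1d (-0.79), Prpsap1 (-0.78), Polb (-0.72), Zfp882 (-0.71), Wsb1 (-0.71), Slc5a3 (-0.68) and Dzip1 (-0.67). Among these, Polb encodes a DNA polymerase of base excision repair, Atp6v1d a subunit of the vacuolar proton pump, and Slc5a3 a myo-inositol transporter. The other rises were Mbip (0.62, SE 0.10) and Aldh5a1 (0.48, SE 0.07), which encodes succinic semialdehyde dehydrogenase of GABA breakdown. Cnr2, the cannabinoid receptor gene known mainly from immune cells, was singled out after its values were seen: its counts were 3, 0 and 5 in controls and 70, 41 and 67 in cKO cortex (adjusted p = 0.0331). It starts 25.5 kb past the end of Srsf10 on the same strand (chromosome 4, 135895394 to 135920207).

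In all, 27 of 15781 tested genes differed between the cortex groups by edgeR at an adjusted p under 0.05, 6 higher and 21 lower in the libraries labelled cKO, and 4 of them, all rises, by at least 2-fold. At an unadjusted p under 0.05 the number was 1719, and DESeq2 called 338 genes. The groups did not overlap for 2730 genes (17.3%, where chance gives 10%). The count rests on single libraries: 0 genes passed without cKO replicate 1, with 1096 at an unadjusted p under 0.05, 1 gene without cKO replicate 3, and 16 without cKO replicate 2. With sex in the model 12 genes passed, and 1 gene with the replicate numbers as a block (the cortex numbers do not pair the libraries). Without the 2 libraries rich in Ttr 22 genes passed, 13 of them among the 27.

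Among 29 gene lists tested in cortex, interneuron and ventral forebrain markers were lower as a group in the libraries labelled cKO, and so were oligodendrocyte lineage markers. Of 16 tested interneuron and ventral forebrain genes 13 had negative values, with a median log2 fold change of -0.29 (camera adjusted p = 0.000778; adjusted p = 0.494 with an estimated correlation). By edgeR none of them passed over all genes tested, 7 fell at an unadjusted p under 0.05 and 6 adjusted over the list alone; DESeq2 called 4 falls over all genes, Dlx1, Dlx2, Lhx6 and Sp8. Dlx1 stood at 118 ± 12.0 CPM in controls and 86.8 ± 6.32 CPM in cKO cortex (log2 fold change -0.45, SE 0.09), Dlx2 at 30.2 ± 5.20 and 20.8 ± 0.509 CPM (-0.54, SE 0.13) and Lhx6 at 90.2 ± 6.27 and 67.7 ± 4.16 CPM (-0.41, SE 0.08), n = 3 each. These 3 genes encode transcription factors of interneuron development. Markers of striatal projection neurons, a list written after the cortex values were seen, had a median of -0.24 over 16 tested genes, a group change that camera did not call. Their median was 0.21 without control replicate 2. The 9 tested oligodendrocyte lineage genes had a median of -0.24 (camera adjusted p = 0.00271; adjusted p = 0.494 with an estimated correlation), and 1 fell over all genes and 2 adjusted over the list alone. That gene was Gpr17, a receptor of differentiating oligodendrocyte precursors, from 25.7 ± 1.31 to 14.8 ± 1.13 CPM, while Olig2 had -0.24 and Pdgfra -0.24, neither past the threshold.

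Targets of the stress-activated transcription factor p53 were higher as a group in cortex labelled cKO. An effect of Nestin-Cre, carried by that group alone, cannot be told apart here from loss of Srsf10. Of 21 tested targets 14 had positive values, with a median of 0.19 (camera adjusted p = 0.00271; adjusted p = 0.494 with an estimated correlation). By edgeR Eda2r rose over all genes, and 6 targets rose adjusted over the list alone; DESeq2 called 5 rises over all genes. The cell cycle inhibitor Cdkn1a stood at 7.0 ± 0.436 CPM in controls and 12.1 ± 1.27 CPM in cKO cortex (log2 fold change 0.79, adjusted p = 0.0706 over all genes by edgeR), Ccng1 had 0.39 and the translesion polymerase gene Polk 0.54. SR protein and Tra2 splicing factor genes other than Srsf10 had a median of -0.10 (20 tested, camera adjusted p = 0.0181; adjusted p = 0.847 with an estimated correlation). By edgeR none passed over all genes, 5 fell at an unadjusted p under 0.05 and 3 adjusted over the list alone, and DESeq2 called 3 falls over all genes. Srsf7 had -0.30, Srsf11 -0.32, Srsf6 -0.25 and Tra2a -0.20. The 13 meningeal fibroblast markers were all positive, with a median of 0.47 (camera adjusted p = 0.0181; adjusted p = 0.938 with an estimated correlation) and 0 past the threshold by edgeR or DESeq2, over all genes or over the list alone (0 and 1 at an unadjusted p under 0.05). Without control replicate 2, where Col1a1 stood at 3.19 CPM against 18.2 and 31.8 CPM in the other controls, the meningeal median was 0.04 (adjusted p = 0.733).

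The other 24 lists tested in cortex had camera adjusted p from 0.125 to 0.949. The lowest belonged to erythroid genes, which had the largest median of all lists (-1.14, 5 of 5 negative). The hemoglobin genes Hba-a1 (12.2 CPM) and Hbb-bs (18.3 CPM) were highest in control replicate 1, Hbb-bs standing at 4.10 to 7.05 CPM in the other 5 cortex libraries. For cell types, the 24 lists covered radial glia, intermediate progenitors, all neurons, deep-layer and upper-layer neurons, Cajal-Retzius cells, choroid plexus, astrocytes, microglia, vessels and erythroid cells. For pathways, they covered both cell cycle lists, CDK inhibitors, hnRNP and neural splicing regulators, Notch, Wnt, cholesterol synthesis and stress responses. Also covered were interferon, immediate early genes, hypoxia and glycolysis, synapses and axon guidance. S phase genes had a median of -0.05 (25 tested, camera adjusted p = 0.142) and G2 and mitosis genes 0.04 (24 tested, 0.676), with 0 past the threshold over all genes by edgeR (4 and 0 at an unadjusted p under 0.05); adjusted over the list alone, 1 S phase gene fell, and DESeq2 called falls of Mcm6 and Pola1 over all genes. Without the libraries rich in Ttr, 0 of the 29 lists passed, and the adjusted p was 0.174 for interneurons, 0.0647 for oligodendrocyte lineage and for p53 targets, 0.129 for SR proteins and 0.608 for meningeal fibroblasts. The medians in those 4 libraries were close to those of all 6 for oligodendrocyte lineage (-0.24) and SR proteins (-0.11), and nearer to 0 for interneurons (-0.16), p53 targets (0.11) and meningeal fibroblasts (0.10). With sex in the model, SR proteins (adjusted p = 0.0812) and meningeal fibroblasts (0.0881) no longer passed. Without cKO replicate 2 these 2 lists had an adjusted p of 0.133, and without control replicate 2 SR proteins had 0.123.

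**Figure D2:**
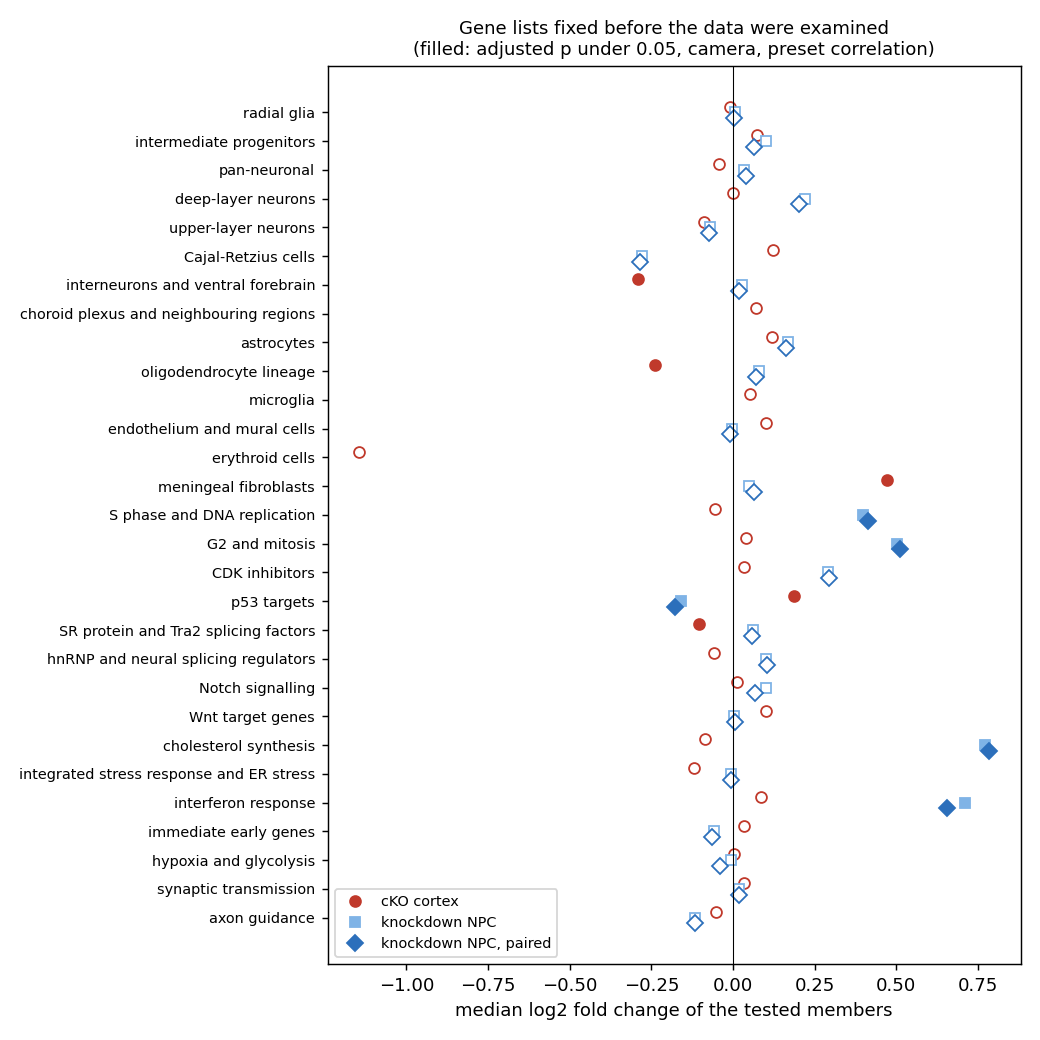
Median log2 fold change of the tested members of each gene list in cortex labelled cKO (circles), NPC labelled knockdown (squares) and the same NPC libraries compared as pairs (diamonds); filled symbols have a camera adjusted p under 0.05 with a preset correlation. Cholesterol synthesis (0.77), interferon response (0.71), G2 and mitosis (0.50) and S phase (0.40) lie to the right in NPC, and interneuron markers (-0.29) lie to the left in cortex.

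In NPC labelled knockdown, 43 genes fell and 5 rose at least 2-fold without pairs, and 107 fell and 93 rose with the replicate numbers as pairs. Genes of the cell cycle and of cholesterol synthesis were higher as groups with a preset correlation (adjusted p = 0.958 with an estimated one). Syt11, a synaptotagmin of vesicle traffic, fell from 1328 ± 186 to 420 ± 85.2 CPM (n = 3 each; log2 fold change -1.66, SE 0.16, adjusted p = 0.00555; paired -1.67). Arhgdia fell from 607 ± 23.9 to 208 ± 33.6 CPM (-1.55, SE 0.11, adjusted p = 0.00555; paired -1.56). The other falls chosen by the fixed rule were Crispld2 (-1.89), Reln (-1.78), which encodes the migration signal reelin, Gpr37 (-1.71), Zfp422 (-1.63), Atmin (-1.57), Mrpl34 (-1.54), Saraf (-1.43), a brake on calcium entry, and Slc18b1 (-1.41). Among the chosen rises, Acot11, an acyl-CoA thioesterase, rose from 10.8 ± 1.48 to 30.0 ± 7.36 CPM (1.48, SE 0.19, adjusted p = 0.0122), followed by Herc6 (1.06), Syne1 (0.999), Fgf14 (0.95), Plekha4 (0.94), Plxnc1 (0.90), Fgf13 (0.88), Rnd1 (0.82), Adcyap1r1 (0.81) and Plxna4 (0.79). Plxnc1 and Plxna4 encode plexins, receptors of axon guidance signals. Nasp had a log2 fold change of 0.27 (SE 0.17, adjusted p = 0.441; paired 0.28, adjusted p = 0.00225).

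Of 14258 tested genes, 270 differed at an adjusted p under 0.05 by edgeR without pairs, 50 higher and 220 lower in the libraries labelled knockdown, 5 and 43 of them by at least 2-fold. DESeq2 called 1012 genes. The hexamers ACCGAC and CCGACT, singled out on these same genes after the data were seen, stood in the annotated 3′ UTR of 111 of 209 searched genes that fell (53.1%) and of 1123 of 10336 searched genes not called (10.9%), which describes the choice and does not test it. A 7-mer that holds ACCGAC, picked on odd-numbered autosomes, was tested on the other chromosomes. There 70 genes with it differed from 4817 without it by -0.33 (log2, permutation p = 1e-05, two-sided). The permutations shuffled genes in 1 fit of the same libraries. This p thus treats genes as independent and does not measure the spread between libraries. The replicate numbers pair the NPC libraries: after each group's mean was removed, same-numbered libraries correlated across genes at 0.48, 0.50 and 0.44. Differently numbered ones correlated at -0.08 or below. Residuals sum to 0 within each group, so these negative values follow from the positive ones and add no separate evidence. With the replicate block 3522 genes differed, 1696 higher and 1826 lower, 93 and 107 of them by at least 2-fold. All 270 were among them in the same direction. DESeq2 with the replicate block called 2437 genes, 1166 higher and 1271 lower. In simulated data 10.9% of the calls of the edgeR fit with the replicate block were false, against 5.77% without pairs. The simulation without pairs held no pair effects, so these shares do not compare the real fits. At 10.9%, the threshold of 0.05 may understate the share of false calls with the replicate block. The common biological coefficient of variation was 0.145 without pairs and 0.0569 with them. Leaving out 1 library gave 47 to 304 genes without pairs (47 without control replicate 3, 55 without control replicate 2, 69 without knockdown replicate 2, 95 without control replicate 1 and 176 without knockdown replicate 3), and leaving out 1 pair gave 1636 to 4376.

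Genes of cholesterol synthesis were higher in NPC labelled knockdown, in every pair for all members but 1. The 18 members had a median log2 fold change of 0.77 (camera adjusted p = 2.58e-08; adjusted p = 0.958 with an estimated correlation). By edgeR without pairs 0 passed over all genes, and 16 rose at an unadjusted p under 0.05 and adjusted over the list alone; DESeq2 without pairs called 14 rises over all genes. With the replicate block 17 rose over all genes by edgeR and the median was 0.78. Hmgcs1, which feeds the mevalonate pathway, stood at 909 ± 221 CPM in controls and 1639 ± 350 CPM in the libraries labelled knockdown (paired log2 fold change 0.86, SE 0.05, adjusted p = 3.52e-07), and Lss, which forms lanosterol, at 93.8 ± 34.0 and 190.3 ± 74.2 CPM (paired 1.01, SE 0.05, adjusted p = 7.15e-08), n = 3 each. The medians in pairs 1, 2 and 3 were 0.68, 0.85 and 0.83.

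Cell cycle genes were higher as well, in 3 of 3 pairs for every tested member of both lists. The 26 S phase genes had a median of 0.40 (camera adjusted p = 2.01e-07; adjusted p = 0.958 with an estimated correlation) and the 24 genes of G2 and mitosis 0.50 (2.01e-07; 0.958 with an estimated correlation). By edgeR without pairs 0 of them passed over all genes or adjusted over the list alone, 11 of each list rising at an unadjusted p under 0.05. DESeq2 without pairs called rises of 4 S phase genes and of 3 genes of G2 and mitosis (Anln, Cdc25c and Hmmr). The control libraries spread widely (Mki67 450.1 ± 141 CPM, n = 3). With the replicate block all 26 and all 24 rose over all genes by edgeR. Among them were Rrm2, a subunit of ribonucleotide reductase (paired log2 fold change 0.69, SE 0.07), the cyclin gene Ccne2 (0.64, SE 0.06), and the mitotic genes Hmmr (0.71, SE 0.06) and Cenpf (0.60, SE 0.05). The S phase medians in pairs 1, 2 and 3 were 0.25, 0.43 and 0.57, and the G2 and mitosis medians 0.45, 0.49 and 0.64.

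**Figure D3:**
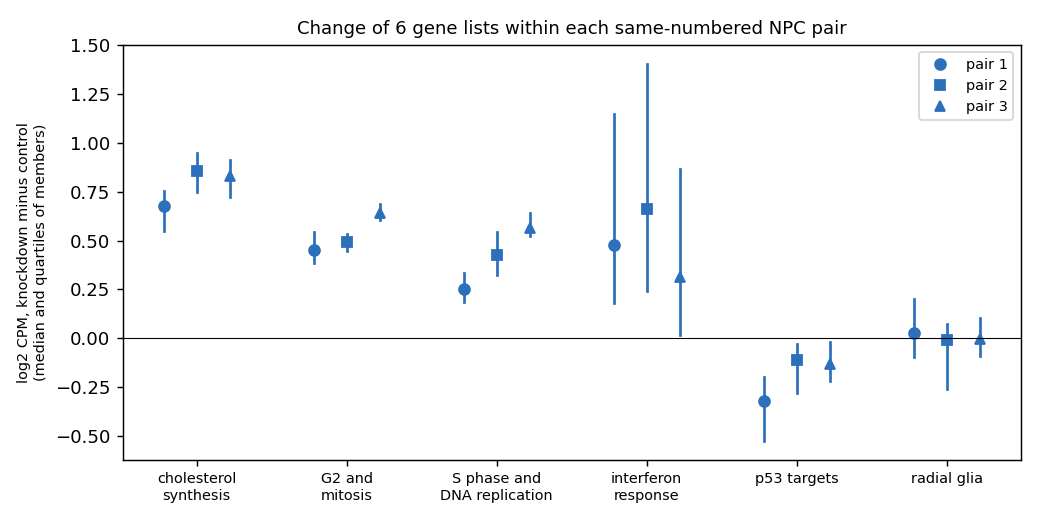
Log2 difference in CPM, labelled knockdown minus control, of 6 gene lists within each same-numbered pair of NPC libraries; symbols mark the median of the list members and lines the quartiles. Cholesterol synthesis and both cell cycle lists lie above 0 in all 3 pairs, and p53 targets lie below it (-0.32, -0.11 and -0.13). The medians of the radial glia markers lie near 0 (0.03, -0.01 and -0.00), with members on both sides.

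Interferon response genes and p53 targets completed the called lists in NPC. The 14 interferon response genes had a median of 0.71 (camera adjusted p = 0.0274; adjusted p = 0.988 with an estimated correlation), with 0 passing by edgeR without pairs, also adjusted over the list alone (3 rising at an unadjusted p under 0.05), and 8 rising with the replicate block. DESeq2 without pairs called Rsad2 alone. Their levels were low: Rsad2 stood at 2.35 ± 0.823 CPM in controls and 8.70 ± 5.43 CPM in the libraries labelled knockdown, and Ifit1 at 0.998 ± 0.823 and 3.78 ± 4.19 CPM (n = 3 each). The 22 p53 targets had a median of -0.16 (camera adjusted p = 0.0154; adjusted p = 0.988 with an estimated correlation), with 0 passing by edgeR without pairs, also adjusted over the list alone (3 falling at an unadjusted p under 0.05), and 10 falling with the replicate block. DESeq2 without pairs called falls of Eda2r, Perp and Sesn2. Among the 10, Cdkn1a stood at 817 ± 127 and 638 ± 163 CPM (paired -0.38, adjusted p = 0.000598) and Sesn2 at 233 ± 30.4 and 164 ± 30.8 CPM (paired -0.52). The interferon list lost its call without control replicate 1 (adjusted p = 0.189), control replicate 3 (0.184), knockdown replicate 1 (0.0711) or knockdown replicate 2 (0.160), and p53 targets without control replicate 3 (0.206) or knockdown replicate 1 (0.701). With the replicate block the 5 lists had camera adjusted p of 0.00329 or less, and adjusted p = 0.805 with an estimated correlation. The other 21 lists had camera adjusted p from 0.213 to 0.984 without pairs and from 0.0822 to 0.983 with them. Radial glia markers had a median of 0.01, but single members changed in both directions. By edgeR with the replicate block 3 of 18 rose over all genes, among them Nes, and 3 fell, among them Sox2. DESeq2 without pairs called the fall of Sox2 alone. Choroid plexus, microglia and erythroid lists had fewer than 5 tested members.

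The changes in the 2 systems shared little. Among 13531 genes tested in both, 19 fell in cortex and 215 in NPC by edgeR without pairs. Of these, 1 was shared, where independent lists give 0.302 (Fisher's exact test, two-sided, p = 0.263, adjusted p = 1 over the direction pairs of all settings). That gene was Slc5a3, with log2 fold changes of -0.68 in cortex and -0.69 in NPC. By edgeR without pairs no rise was shared and no gene was called in opposite directions. DESeq2 without pairs shared 10 falls and 4 rises (Aldh5a1, Ercc6l2, Gen1 and Lmo3) and called 6 genes in opposite directions (Eda2r, Sesn2 and Cdh4 higher in cortex, Clmp, Fam110a and Pcyt2 lower), each adjusted p = 1 by Fisher's exact test. With the replicate block in NPC alone, by edgeR, Aldh5a1 rose and Atp6v1d, Slc5a3 and Wsb1 fell in both, while Eda2r, Nasp and Gm10052 went opposite ways. Independent lists give 0.612 shared rises and 2.51 shared falls in this setting. They give 0.661 genes higher in cortex and lower in NPC, and 2.33 the other way. Across genes, which are not independent replicates, the fold changes correlated at r = 0.0543 (Pearson) and 0.0642 (Spearman's rank correlation). In a test of the difference between systems, 242 of 16569 genes passed, 81 with a more positive change in NPC and 161 with a more negative one. The fit leaves out the NPC pairs: with the replicate block 604 passed (283 and 321), by DESeq2 783 (323 and 460), and without 1 library 98 to 275. Eda2r was among them (NPC minus cortex -2.46, SE 0.30, adjusted p = 0.00217), as was Reln (-1.89, SE 0.23, adjusted p = 0.00219), which had 0.14 in cortex. Lists tested for the difference gave camera adjusted p of 3.44e-10 for cholesterol synthesis, 2.69e-08 for S phase, 9.20e-06 for G2 and mitosis, 5.34e-05 for p53 targets and 0.0170 for SR proteins, each with adjusted p = 0.927 with an estimated correlation.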

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

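The tests of explanations in this part, other than the counts over other groupings of the libraries, were chosen after the results were seen. The test of the difference between the systems picked out 242 genes. Of 60 groupings of the libraries, 1 gave as many, the real one, and the highest of the others gave 154. This share does not settle the cortex part: the groupings did not hold to the NPC pairs, and those with the highest counts kept the NPC groups. With the NPC groups kept, all 20 ways to label the cortex libraries, counted after this was seen, gave 106 to 316 genes, and 2 gave 242 or more, the real one and the one with the cortex labels swapped. The count thus rests mostly on the NPC libraries, and chance is not excluded for what cortex adds.

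Differences below are log2, NPC minus cortex. For Eda2r the difference was -2.46, with a rise in cortex and, in pairs, a fall in NPC. For Reln it was -1.89 and for Crispld2 -1.97, both called falls in NPC with values of 0.14 and 0.10 in cortex. For Clmp it was 1.64, with 232 ± 3.57 CPM in control cortex and 0.790 ± 0.0452 CPM in control NPC (n = 3 each). For Slc26a7 it was 2.91, a called fall in cortex, and the gene was too low in NPC to be tested there. Cdk2ap2 had -3.67, a called fall in NPC and a level of 0.0819 ± 0.0722 CPM in control cortex. Shisa3 had -2.85 (0.88 lower in NPC, called, and an uncalled 1.99 in cortex). Uqcrc1 had 2.93, Rec8 2.37 and Celrr 1.57, none of them called within either system. Uqcrc1, a subunit of mitochondrial complex III, stood at 5.72 ± 4.29 CPM in control cortex and 303 ± 15.4 CPM in control NPC (n = 3 each). Whether reads were assigned to genes alike in both systems was not tested, which bears on levels such as those of Uqcrc1 and Clmp.

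Genes with a certain short sequence in their 3′ UTR lay lower in NPC labelled knockdown than genes without it. The 3′ UTR is the part through which a short RNA can lower transcripts other than its target. The RNA pairs there through the bases near its 5′ end, the seed. On odd-numbered autosomes the 7-mer GACCGAC marked the lowest genes, and on the other chromosomes 70 genes with it lay at -0.33 ± 0.40 (mean ± SD, log2, paired fit) against 0.00 ± 0.26 for 4817 genes without it, a difference of -0.33 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations give), while its reverse complement GTCGGTC gave -0.00 (permutation p = 0.990) and the same 7-mer in cortex -0.02 (permutation p = 0.393). These p-values come from permutations of genes, which are not independent replicates, and do not measure the spread between libraries. The chromosomes tested share their NPC libraries with those used for picking. Adjusted for 3′ UTR length, GC content and expression the difference in NPC was -0.32, which argues against those properties as its source. Silencing of other transcripts by a knockdown RNA may therefore underlie part of the falls, as a hypothesis: Srsf10 itself holds GACCGAC (chromosome 4, 135863528 to 135863534, in exon 5 of its 4 coding transcripts that hold it), as do 7.12% of tested genes, and the sequence of the knockdown RNA is not given in the sources used here. Loss of the Srsf10 transcript below 0.865 of control lies outside the NPC interval. A smaller loss and a loss of single transcripts, of protein or of function were not tested and stay open. The labels give the same infection (72 h, multiplicity of 30) for both NPC groups, which argues against infection as such. What the control virus carried is not given in the sources used here, so an effect of viral content stays open. The 215 fallen genes tested in cortex had a median there -0.00705 apart from the other genes (log2). In that tissue the count does not show that Srsf10 was lost.

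Interneuron and ventral forebrain markers were lower in cortex labelled cKO (median -0.29). Unequal numbers of females and males as the whole source is argued against, since with sex in the model the median was -0.30 (adjusted p = 0.000615; adjusted p from 9.69e-05 to 0.494 over the alternatives of this list). More ventral tissue in the control dissections could not be excluded: striatal projection neuron markers, none of them in the list, had a median of -0.24 with 15 of 16 negative, but a camera p of 0.308 (0.771 with an estimated correlation), and 0.21 without control replicate 2, where the interneuron list stayed lower (-0.20, adjusted p = 0.0237), while without both libraries rich in Ttr it lost its call (-0.16, adjusted p = 0.174). By library, the mean log2 deviations of the 2 lists were both highest in control replicate 2 (striatal 0.86, interneuron 0.33), but control replicate 3 had the lowest striatal value (-0.74) and an interneuron value (-0.01) above all cKO libraries, and cKO replicate 1 ran the other way (0.31 and -0.12). The bound written for this test, a p of 0.05 or more, was met, but a missed threshold does not show that values did not differ and single libraries settle neither side, so fewer interneurons in mice labelled cKO stays open as the biological explanation beside the dissection.

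Cnr2 was 4.44 higher (log2, SE 0.66) in cortex labelled cKO, 178 counts over 3 libraries against 8, with adjusted p from 3.44e-07 to 0.240 over its alternatives. More microglia in those samples is argued against: 12 tested microglia markers had a median of 0.0517 (log2) and none passed, the chemokine receptor Cx3cr1 standing at 16.7 ± 1.44 CPM in control cortex (n = 3). The other 9 tested genes within 200 kb of Srsf10 lay within 0.31 of 0, with adjusted p of 0.392 or more by edgeR. Pnrc2, between the 2 genes on the opposite strand, had -0.13. These values argue against a wider domain raised by a fold like that of Cnr2. They cannot exclude a like gain in counts, because neighbours such as Fuca1 (3730 counts in controls, 3475 in cKO cortex) hold far more. Neighbours with very low counts, such as Ifnlr1 (19 and 33), were not tested. A sequence difference on chromosome 4 that travels with the floxed allele was not tested, and both cortex groups carry that allele per the labels.

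Other groupings were counted for the remaining results, where 3 libraries against 3 allow 10 groupings and pairs allow 4, too few for a share under 0.05. For cortex genes 1 of 10 groupings gave as many as the real 27, the highest other giving 6; for NPC genes 1 of 10 gave as many as 270, and for the paired NPC genes 1 of 4 gave as many as 3522, the highest other giving 0 in both. The 4 NPC groupings that part all pairs, the real one included, are the 4 of the paired test, and the other 6 keep 2 pairs together. For gene lists called with the preset correlation, 7 of 10 groupings in cortex, 6 of 10 in NPC and 3 of 4 in paired NPC gave as many as the real 5, the highest others giving 10, 11 and 6. List calls of this kind thus did not set the real groups apart from others.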

How the results depend on the processing

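Sex as a covariate, leaving out the libraries rich in Ttr, every alternative of the paired NPC result, the overlap with the block in NPC alone and the removal of hexamer genes were chosen after seeing the data; the others were planned. Over all alternatives no called gene among those named and no called list changed sign, while the uncalled Srsf10, Ttr and Ddx3y did in some, Srsf10 staying uncalled; the correlation across genes between the systems did, from 0.0543 to -0.0665 among genes called in either system, and the cause was not tested.

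The cortex count of 27 was 156 without the count filter, 338 by DESeq2, 49 with all 12 libraries in 1 fit, 1 with the replicate block, 12 with sex and 0 to 28 without 1 library. The NPC count of 270 was 1012 by DESeq2, 654 in 1 fit of all libraries, 3522 with the replicate block (paired), 160 at a 1.5-fold minimum and 47 to 304 without 1 library. The paired count of 3522 was 2437 by DESeq2, 699 at a 1.5-fold minimum and 2874 without genes carrying the hexamers. Without 1 pair it was 1636 to 4376, with 2170 without pair 2. The interaction count of 242 was 783 by DESeq2, 604 with the replicate block and 98 to 275 without 1 library. The causes were not tested, except that fits without a library have fewer samples and the fold minimum removes genes by construction. RLE size factors kept every count within 1.5 times (28, 265, 3489 and 235).

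The 5 lists called in cortex became 0 with an estimated correlation, 0 by directional fry, 0 without the libraries rich in Ttr, and 3 to 6 without 1 library. The 5 in NPC became 0 with an estimated correlation, 0 by directional fry and 3 to 5 without 1 library. In paired NPC the 5 became 0 with an estimated correlation and 5 without any 1 pair. Directional fry gave 3 there, of which only cholesterol synthesis is among the 5. The single gene shared by both systems became 14 by DESeq2, 0 with the replicate block in both and 4 with the block in NPC alone. Of the alternatives for named genes, 430 in cortex, 411 in NPC and 411 in paired NPC kept the side of the threshold, while 83, 57 and 17 lost the call and 18 and 48 (cortex and NPC) gained it. Depth limits genes such as Cnr2, whose control counts were 3, 0 and 5.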

Other observations

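Without the genes whose 3′ UTR holds ACCGAC or CCGACT, the paired NPC comparison called 2874 genes, 1552 higher and 1322 lower. In the paired comparison 26.2% of the genes that fell carried a hexamer, against 6.49% of those that rose and 9.39% of those not called; the hexamers were picked on these same genes, so the shares are a description.

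The choroid plexus and midbrain gene Otx2 stood at 14.4 ± 7.33 CPM in control NPC and 29.8 ± 17.9 CPM in NPC labelled knockdown (n = 3 each; paired log2 fold change 1.01, SE 0.08, adjusted p = 2.70e-06; without pairs adjusted p = 0.293). Gm10052, an unnamed gene model, moved beside Nasp in both systems, with log2 fold changes of -0.57 in cortex (adjusted p = 0.0231) and 0.27 in paired NPC (adjusted p = 0.00262; without pairs 0.28, adjusted p = 0.319). Nasp had -0.58 in cortex and 0.28 in paired NPC (adjusted p = 0.00225; without pairs 0.27, adjusted p = 0.441). By edgeR both NPC changes thus passed only with the replicate block. In cortex Gm10052 stood at 196 ± 16.1 CPM in controls and 132 ± 9.10 CPM in cKO, near Nasp at 230 ± 6.05 and 153 ± 7.07 CPM (n = 3 each). Whether the 2 share reads was not tested, so they may not be separate changes.

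Levels of some abundant genes differed widely between the systems. Srsf1 stood at 7.16 ± 1.09 CPM in control cortex and 514 ± 66.7 CPM in control NPC, Fdps at 182 ± 22.1 and 4.15 ± 1.89 CPM, and Gapdh at 20.5 ± 2.30 and 70.1 ± 6.19 CPM (n = 3 each). The counting program and annotation are not given in the sources used here, and whether reads were assigned to genes alike in both systems was not tested.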
